A study of Pseudofrankia inefficax with 9 samples.

How the data were processed

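RNA was measured in cultures of strain EuI1c of Pseudofrankia (Frankia) inefficax, an actinobacterium from plant root nodules. Per the labels, cultures were grown for 3 days at 30 °C in MP medium with glucose, with glucose plus 1 mM biphenyl, or with 1 mM biphenyl as the sole carbon source. Biphenyl is a hydrocarbon of a pair of linked benzene rings and a common environmental pollutant. Per the labels, total RNA was extracted with the RNeasy kit, stable RNA was depleted with the MICROBExpress kit, and Illumina libraries were made. Per the labels of the series, reads were mapped to the EuI1c genome with CLC Genomics software. Its version, its settings and whether counting used strand are not given in the sources used here.

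The deposited table of each library holds 7152 genes with their coordinates on 1 chromosome. Per the file headers, each gene has a total read count, a unique read count, a TPM value and an RPKM value. The counts are whole numbers and were not normalized by the authors. TPM is normalized by the authors for gene length and library total, and was used in 1 alternative. The deposited RPKM columns hold 0 in every row and were not used. The tables give a gene symbol for 47 genes and a locus identifier for the other 7105. They do not pair identifiers with gene products, so at most 2 identifiers of each direction are printed and other genes are given by coordinates. No genome or annotation was used here beyond the coordinates in the tables. Of the coding lengths, 99.1% are multiples of 3 bp.

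There were 3 groups of 3 libraries. The titles give each library a batch number from 1 to 3, with 1 library of each group in each batch. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be partly technical. No replicate pair agreed within sampling noise: the chi-square per degree of freedom over genes ran from 1.79 to 8.04.

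In 6 rows, over 95% of reads were shared with another place in the genome and each row held at least 0.1% of all reads. They form 3 copies each of a 3137 bp and a 1510 bp gene. The tables do not annotate them, and they are called multicopy rows here. They were left out of library sizes and tests, which left 7146 genes. Rows for tRNA could not be picked out without product names. After this step a library held between 91038 and 196363 reads, so a count of 0 allows up to 15.3 CPM in the deepest and 33.0 CPM in the shallowest library, taking 3 reads as the limit. Intervals and limits cover counting error only.

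The main test was edgeR's quasi-likelihood F test with TMM factors, the default filter of filterByExpr, and Benjamini-Hochberg adjustment at 0.05. All 9 libraries entered 1 group-means model, without batch. The filter kept 3143 genes. CPM values of genes are relative to the reads of those 3143 genes after TMM scaling. The standard error of a log2 fold change is its absolute value divided by the square root of F. Tools were R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, limma 3.58.1, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. The design and the alternatives were fixed before the data were examined. The design set out to remove rows annotated as rRNA or tRNA. Without such annotation, the rule for multicopy rows took the place of that step. The batch numbers pair the libraries because the labels name them as batches. Deviations from group means of same-batch biphenyl libraries correlated at 0.614 in batch 1, 0.495 in batch 2 and -0.109 in batch 3. Between controls and same-batch biphenyl libraries the correlations lay between -0.0407 and 0.202. A model with batch as a block, which left 4 residual degrees of freedom in place of 6, is given beside a result where it changes calls. The batch term itself passed in 63 genes.

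The rule for named genes took, per comparison, the 10 largest changes in each direction among genes that passed with groups that did not overlap. Where fewer than 5 passed, it took the 5 genes of smallest p as not passing, and this applied to all 3 comparisons. Other genes and regions named were chosen after their values were seen. The same rule fixed 34 gene lists by words in gene products. Since the tables carry no product text, 32 of them had no member, the chaperone list had 3 (groEL_1, dnaK and groEL_2) and the iron-sulfur list had 1 (sufC). No list reached the 5 members needed for a set test. The 47 symbols were sorted into 8 functional groups after the symbols were seen and before any test. Groups with 5 or more tested members were tested with camera (preset correlation 0.01) and fry. Runs of neighbouring genes on one strand, at most 100 bp apart, were summed and tested the same way, a unit chosen after seeing the data.

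The same code was tested on simulated counts drawn from the real gene means, library sizes and dispersions, with 200 of 3143 genes changed. For biphenyl plus glucose against control it recovered 74% of genes changed 4-fold and 7% of those changed 2-fold. For biphenyl alone against control the shares were 77% and 6%, and for biphenyl alone against biphenyl plus glucose 68% and 11%. False calls numbered 4, 3 and 2. With the batch block 70%, 70% and 58% of genes changed 4-fold were recovered in these comparisons. The simulated libraries had the same dispersion of a gene in all groups and no batch. Real biphenyl libraries included pairs that differed more than any control pair, so these shares and false calls may be too favourable for the real data. Alternatives were the batch block, DESeq2's and upper-quartile size factors, DESeq2, limma-voom, other count filters, only the groups compared, a minimum fold change, multicopy rows kept, unique reads, limma on log2(TPM + 1) and leaving out each library. Added after seeing the data were runs of genes, a length trend removed per library by offsets, and subtraction from each library of a background proportional to gene length, at the read density of its 714 least expressed genes.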

Results

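Transcript levels were measured in 9 libraries of strain EuI1c, 3 each from glucose cultures (control), glucose cultures with 1 mM biphenyl (biphenyl plus glucose) and cultures with biphenyl as sole carbon source (biphenyl alone). The study asked how the transcriptome under biphenyl differs from that without it. Libraries held between 2696113 and 5414721 counted reads. The 6 multicopy rows took 96.3% ± 0.265 (SD, n = 3) of reads in controls, 97.4% ± 0.731 with biphenyl plus glucose and 95.7% ± 1.25 with biphenyl alone. That left 174353 ± 19611 reads per library for all other genes in controls, 104531 ± 23113 with biphenyl plus glucose and 135894 ± 26734 with biphenyl alone (SD, n = 3). The control libraries therefore carried the most precise values, and at this depth 2-fold differences were mostly not detectable in simulated data.

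Some measures of how reads were spread differed between groups, and none of them measures RNA quality directly. The 714 least expressed genes, chosen for each library from the other 8, carried 4.47 ± 0.408 CPM per kb, relative to reads outside the multicopy rows, in controls, 6.40 ± 1.06 with biphenyl plus glucose and 10.7 ± 6.60 with biphenyl alone (SD, n = 3). Biphenyl alone replicate 3 stood apart at 18.0, with 330 genes at 0 reads against 727 to 1351 in the other libraries. The ratio of reads on the 1510 bp to the 3137 bp multicopy genes was 0.186 ± 0.0132 in controls, 0.165 ± 0.0333 with biphenyl plus glucose and 0.141 ± 0.00930 with biphenyl alone (SD, n = 3). Biphenyl alone did not overlap the controls in this ratio (two-sided exact permutation p = 0.1, the smallest that 3 against 3 libraries can give), while biphenyl plus glucose did (exact permutation p = 0.5).

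**Figure D1:**
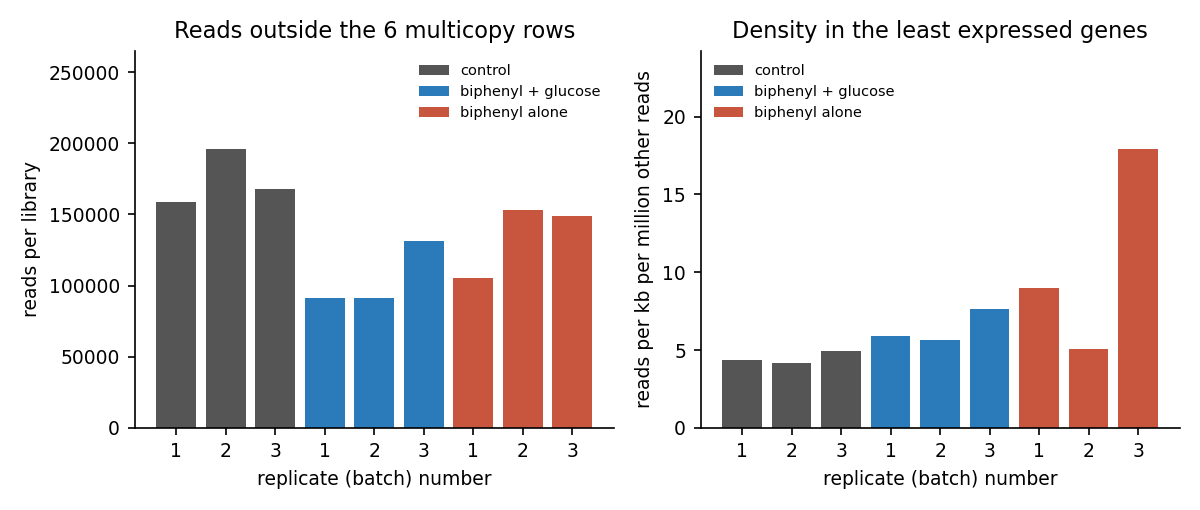
Reads outside the 6 multicopy rows per library (left) and CPM per kb in the least expressed genes (right), 1 bar per library, coloured by group, with replicate numbers on the horizontal axis. All 6 biphenyl libraries lie below the 3 controls on the left and above them on the right, where biphenyl alone replicate 3 reaches 18.0.

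Among genes with symbols, 2 belong to a class that cleaves aromatic rings. The genes mhpB_1 (4985774 to 4986712, minus strand) and mhpB_2 (6557692 to 6558609, plus strand) carry the symbol of an extradiol dioxygenase, which opens catechol-type rings. They were picked after the symbols were seen. Over all 9 libraries mhpB_1 had 32 reads and mhpB_2 had 49, too few for the test. With biphenyl alone, mhpB_1 was at 35.5 ± 10.7 CPM against 26.3 ± 12.9 in controls, and mhpB_2 at 33.1 ± 20.1 against 42.1 ± 14.1 CPM (SD, n = 3). Neither difference exceeded the spread between libraries.

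The first comparison addressed what biphenyl does while glucose is present. No gene passed the test. The smallest p belonged to FRAEUI1C_RS24605 (6099428 to 6100951, plus strand, 1524 bp), at 1482 ± 1387 CPM with biphenyl plus glucose against 207 ± 27.2 in controls (SD, n = 3). Its log2 fold change was 2.83 ± 0.56 (SE), with an adjusted p of 0.3003 in edgeR. Its libraries were at 3070, 509 and 868 CPM, and without biphenyl plus glucose replicate 1 the log2 fold change was 1.75 and did not pass. With batch as a block this gene passed, with a log2 fold change of 2.61 ± 0.47 (SE) and an adjusted p of 0.00975. A second gene at 5586992 to 5588191 (plus strand, 425 ± 169 against 103 ± 74.7 CPM) passed in the blocked model alone, at 2.13 ± 0.43 on the log2 scale and an adjusted p of 0.0361; without control replicate 2 and without the block its log2 fold change was 2.66. After a flat background was subtracted in the blocked model, over the same genes, FRAEUI1C_RS24605 passed, at 2.66 ± 0.48 on the log2 scale and an adjusted p of 0.0411. The gene at 5586992 did not pass then, with an adjusted p of 0.178, although its log2 fold change was 2.22 ± 0.48 (SE) and so no smaller than before.

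The remaining 3 genes of smallest p did not pass in either model. The gene at 4833899 to 4834771 (minus strand) had a log2 fold change of -1.36 ± 0.34 (SE), and those at 6527442 to 6529145 (minus strand) and 5579014 to 5581458 (plus strand) had 1.54 ± 0.39 and 1.37 ± 0.36. Summed as runs, 3 regions passed with the block. These were 6099428 to 6101500 (2 genes), the single gene at 5586992, and 8327323 to 8332388 (minus strand, 3 genes), where the run measured 139 ± 51.2 CPM against 22.9 ± 9.24 in controls (SD, n = 3). The last had a blocked log2 fold change of 2.54 ± 0.55 (SE) and an adjusted p of 0.0351. Over its length a flat background at the density of the least expressed genes amounts to 36.7 CPM with biphenyl plus glucose and 24.0 CPM in controls, at or above its whole control level. After that background was subtracted, 1 of the 3 regions passed, that at 6099428 (2.68 ± 0.48, SE, adjusted p 0.0214). The region at 8327323 was then at 4.32 ± 0.95 with an adjusted p of 0.111, and that at 5586992 at 2.26 ± 0.47 with an adjusted p of 0.0997. The value of 4.32 has no firm size, since subtraction leaves almost no control reads in that region.

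No named gene of central metabolism or protein folding passed the test. The chaperone genes groEL_1 and dnaK, whose products fold proteins, were at 20295 ± 3537 and 7642 ± 774 CPM against 21684 ± 1260 and 8157 ± 444 in controls (SD, n = 3). The dnaK values are uncertain, since 29.7% of its reads map to other places as well. Of the 3 genes of the chaperone list, 0 passed over all genes and 0 adjusted over the list alone. The glycolytic genes pgi (glucose-6-phosphate isomerase) and eno (enolase) had log2 fold changes of 0.11 and -0.06. The succinate dehydrogenase gene sdhA_1 was at 1039 ± 204 against 684 ± 216 CPM (SD, n = 3), with each of its 3 libraries above the controls, a log2 fold change of 0.60 ± 0.41 (SE) and an adjusted p of 0.989. It was 0.38 without control replicate 3. The other copy, sdhA_2, had 0.33 ± 0.44 (SE) and did not pass. Of the 7 genes of glycolysis and the TCA cycle, 0 passed. The iron-sulfur assembly gene sufC had a log2 fold change of 0.18 and did not pass, alone or over all genes. None of the 4 symbol groups large enough for camera or fry passed (smallest adjusted p 0.923 with camera).

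In all, edgeR called 0 of 3143 genes, with 143 at an unadjusted p under 0.05 where 157 were expected. Splits of the same 6 libraries that mix the groups gave between 49 and 269 such genes, so 157 is no firm chance value. DESeq2 called 1 gene, limma-voom 0, limma on deposited TPM 0, and edgeR with the batch block 2, both higher. Groups did not overlap in 350 genes (11.1%), where chance gives 10%. Leaving out control replicate 1 or biphenyl plus glucose replicate 2 gave 1 call each.

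The second comparison addressed growth on biphenyl as the only carbon source against growth on glucose. No gene passed without the batch block, and 61 passed with it, of which 44 fell and 17 rose. The block assumes that all 3 groups share batch deviations. The covariance of these deviations was 0.162 between the biphenyl groups. It was 0.0302 between biphenyl alone and control, and 0.0255 between biphenyl plus glucose and control. With the block the common dispersion fell from 0.111 to 0.0797. The spread used may therefore be too small for comparisons with control, and the 61 calls too many. The smallest p belonged to FRAEUI1C_RS04270 (1077014 to 1077571, minus strand, 558 bp), at 192 ± 39.4 CPM against 1001 ± 65.5 in controls (SD, n = 3). Its log2 fold change was -2.38 ± 0.40 (SE), with an adjusted p of 0.0506 in edgeR and 0.00142 with the block. FRAEUI1C_RS09370 (2301628 to 2302812, plus strand) was at 190 ± 50.6 against 840 ± 55.5 CPM, with a log2 fold change of -2.15 ± 0.39 (SE) and the same pair of adjusted p-values. In both genes all 3 biphenyl alone libraries lay below all 3 controls. The 3 biphenyl plus glucose libraries did so as well, at 526, 254 and 683 CPM in FRAEUI1C_RS04270 and 476, 280 and 646 CPM in FRAEUI1C_RS09370. The lower values are thus not particular to cultures without glucose, although neither gene passed in biphenyl plus glucose against control.

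The other genes of smallest p also lay lower with biphenyl alone, and each passed with the block at an adjusted p of 0.00372. They were 4833899 to 4834771 (minus strand, log2 fold change -1.78 ± 0.34), 7009006 to 7010145 (plus strand, -1.95 ± 0.38) and 1940353 to 1941288 (minus strand, -2.02 ± 0.41, SE). The neighbour of the gene at 1077014, at 1077753 to 1078337 on the same strand, fell with the block from 2972 to 899 CPM in mean value. The deepest blocked fall among the 44 was that of a 276 bp gene at 522639 to 522914 (plus strand). Its blocked log2 fold change was -3.58 ± 0.65 (SE), with an adjusted p of 0.00241. Its libraries were widely scattered, at 126 ± 146 CPM with biphenyl alone against 840 ± 581 in controls (SD, n = 3). Without the block edgeR gave -2.78 ± 0.96 (SE) and an adjusted p of 0.219.

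Long neighbouring regions were among those that rose with the block. A run of 5 genes over 26.6 kb at 3732497 to 3759098 (minus strand) was at 634 ± 394 CPM against 164 ± 9.73 in controls (SD, n = 3), a blocked log2 fold change of 1.82 ± 0.38 (SE). Over this length a flat background at the density of the least expressed genes amounts to 261 CPM with biphenyl alone and 126 CPM in controls. A single gene of 25.4 kb at 3855147 to 3880538 (plus strand) had 1.33 ± 0.37, and the adjacent gene at 3880637 to 3889861 (minus strand) 1.56 ± 0.41. A run of 10 genes at 7171215 to 7180643 (plus strand) was at 188 ± 76.8 against 44.2 ± 18.1 CPM, with 2.07 ± 0.47, where that background amounts to 89.6 and 43.1 CPM, close to the whole level in controls. The regions 6099428 to 6101500 and 8327323 to 8332388, which had passed with biphenyl plus glucose, passed here as well, at 1.79 ± 0.43 and 2.31 ± 0.53. Of 2775 runs, 70 passed with the block, 26 higher and 44 lower, and 1 passed without it, the run of the single gene at 1077014. After background subtraction 6 of the 26 higher and 20 of the 44 lower runs passed with the block. The log2 fold change was larger after subtraction in all 26 higher runs (median 1.73 before and 2.09 after), and so was the median SE (0.45 before and 0.59 after). The larger fold was fixed in advance, since the lowest of the 26 (1.256) exceeded the background's own log2 ratio. That ratio was 1.253 before TMM scaling and lower on the scale of the folds, where the background at 3732497 was 261 against 126 CPM. The regions at 3732497, 6099428 and 8327323 passed after subtraction. Those at 3855147, 3880637 and 7171215 did not, at 1.82 ± 0.53, 2.20 ± 0.61 and 3.38 ± 0.98 (SE) on the log2 scale. At 8327323 and 7171215 the subtracted background is above or close to the whole control level, so their folds after subtraction have no firm size.

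Among genes with symbols, ppnK (2126561 to 2127436, plus strand), encoding NAD kinase, was at 140.5 ± 14.4 CPM with biphenyl alone, 90.8 ± 9.70 with biphenyl plus glucose and 51.2 ± 5.15 in controls (SD, n = 3). Its log2 fold change against control was 1.45 ± 0.39 (SE), with adjusted p-values of 0.143 over all genes, 0.0666 with the block and 0.0109 over the 6 tested nucleotide and cofactor genes alone, a group made after the symbols were seen. It rests on 103 reads in all libraries together. The 4 genes of protein folding and turnover had log2 fold changes from -0.59 (dnaK) to -0.17 (groEL_2), negative under every scaling tried, and none passed. groEL_1 was at 10633, 28607 and 5750 CPM in biphenyl alone replicates 1, 2 and 3, against 21684 ± 1260 in controls (SD, n = 3). Their median was -0.44, and -1.15 without biphenyl alone replicate 2, where 2 passed, groEL_1 (-1.48 ± 0.37, SE, adjusted p 0.0293) and clpP. It was -0.21 without biphenyl alone replicate 1 and -0.10 without biphenyl alone replicate 3, each with 1 gene positive. The chaperone list gave 0 calls over all genes and 0 adjusted over the list alone.

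In glycolysis and the TCA cycle, 5 of 7 genes had negative log2 fold changes and 0 passed, among them pgi at -0.58 ± 0.34, eno at -0.53 ± 0.37 and acnA (aconitase) at -0.61 ± 0.44 (SE). The smallest adjusted p of the 7, 0.399, belonged to a gene of the opposite sign, the succinate dehydrogenase gene sdhA_2, at 684 ± 348 against 377 ± 126 CPM (SD, n = 3), with a log2 fold change of 0.86 ± 0.43 (SE). Its value was 1.13 without biphenyl alone replicate 2 (adjusted p 0.0666), 0.44 without biphenyl alone replicate 1 and 0.57 without control replicate 2. The median of the 7 was -0.39, and -0.88 without biphenyl alone replicate 2, where pgi and eno were each at -0.88 and acnA at -1.21 (adjusted p 0.0659). It was -0.23 without biphenyl alone replicate 1, -0.16 without control replicate 2 and -0.16 without biphenyl alone replicate 3, where 4 of 7 were negative and acnA was at -0.34. None of the 7 passed in these fits. The elongation factor gene fusA was at 6670 ± 3956 against 8088 ± 930 CPM in controls (SD, n = 3). Of 8 tested translation genes, 6 had negative values, 5 with upper-quartile factors, and 0 passed. Biphenyl alone replicate 2 lay above the control mean in all 8, replicate 1 in 0 and replicate 3 in 1. The median log2 fold change was -0.25. Without replicate 2 all 8 were negative (median -0.94) and the ribosomal protein gene rplS passed (-1.32 ± 0.38, SE, adjusted p 0.0464), while the median was 0.02 without replicate 3 (5 positive) and -0.12 without replicate 1 (3 positive). No symbol group passed camera or fry (smallest adjusted p 0.310 with fry, and 0.192 with fry and the block).

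**Figure D2:**
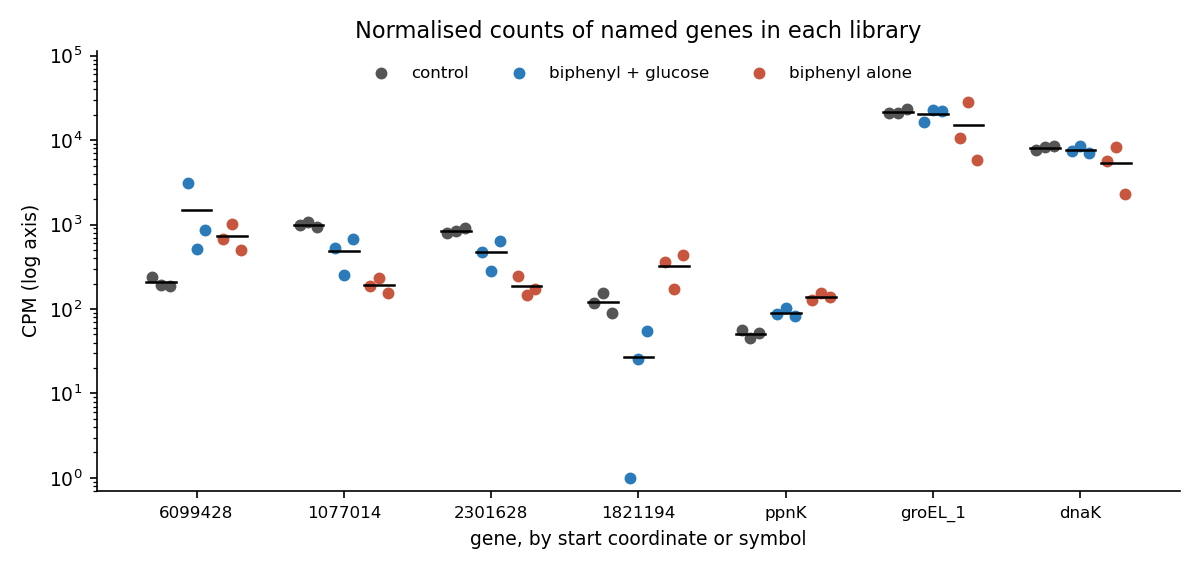
CPM on a log axis for 4 genes given by start coordinate and for ppnK, groEL_1 and dnaK, 1 point per library, coloured by group, with black lines at group means. A value of 0 is drawn at 1. At 1077014 and 2301628 the 3 biphenyl alone libraries lie below all others, while groEL_1 spans 5750 to 28607 CPM within biphenyl alone.

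In all, edgeR called 0 of 3143 genes without the block, with 427 at an unadjusted p under 0.05 where 157 were expected. Splits of the same 6 libraries that mix the groups gave between 24 and 298 such genes, so 157 is no firm chance value. DESeq2 called 20, limma-voom 4 and limma on deposited TPM 0. Groups did not overlap in 630 genes (20.04%), where chance gives 10%. The 44 genes that fell with the block had a median coding length of 546 bp and the 17 that rose 1524 bp, against 1068 bp over tested genes.

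Single libraries decided how many genes passed. Without the block, 253 passed when biphenyl alone replicate 2 was left out (151 higher, 102 lower), 44 without biphenyl plus glucose replicate 1, 15 without biphenyl plus glucose replicate 2, 6 without biphenyl alone replicate 1 and 1 without control replicate 1. With the block, 235 passed without biphenyl alone replicate 2 and 12 without biphenyl alone replicate 3, the library with the most reads in the least expressed genes.

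The third comparison set biphenyl alone against biphenyl plus glucose, that is, the loss of glucose in the presence of biphenyl. FRAEUI1C_RS07330 (1821194 to 1823167, plus strand) was at 324 ± 137 CPM with biphenyl alone against 26.9 ± 27.7 with biphenyl plus glucose (SD, n = 3), and at 121 ± 32.0 in controls. Its log2 fold change was 3.43 ± 0.59 (SE), with an adjusted p of 0.0595 in edgeR and 0.00135 with the block, and it was the 1 gene to pass with the block. The 3 biphenyl plus glucose libraries held 0, 2 and 6 reads of it. Its log2 fold change was 2.80 without biphenyl plus glucose replicate 1 and 4.51 without biphenyl plus glucose replicate 3. Since 81.5% of its reads map to other places as well, the value is uncertain for this copy.

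The next genes of smallest p did not pass in either model. They were 7855731 to 7857380 (plus strand, log2 fold change 1.61 ± 0.39), 1940353 to 1941288 (minus strand, -1.61 ± 0.41), 4120693 to 4122492 (minus strand, 2.32 ± 0.61) and 7928832 to 7930277 (plus strand, 2.15 ± 0.58, SE). The gene at 1940353 is also among those that fell against control with the block. The 8 tested translation genes all had negative log2 fold changes, under every scaling tried, with a median of -0.33, and 0 passed. Biphenyl alone replicate 2 stood apart, above the biphenyl plus glucose mean in all 8, where replicate 1 lay above it in 0 and replicate 3 in 1. In fusA, biphenyl alone replicates 1, 2 and 3 were at 5002, 11187 and 3821 CPM, against 8241 ± 2358 CPM with biphenyl plus glucose (SD, n = 3). The median was -1.02 without biphenyl alone replicate 2, -0.02 without biphenyl alone replicate 3 (3 genes positive) and -0.14 without biphenyl alone replicate 1 or without biphenyl plus glucose replicate 2 (2 positive each). It was -0.56 without biphenyl plus glucose replicate 1 and -0.22 without biphenyl plus glucose replicate 3 (1 positive). None of the 8 passed in these fits. As a group, with all libraries, they gave an adjusted p of 0.0780 with camera, and an adjusted p of 0.420 with an estimated correlation. The succinate dehydrogenase gene sdhA_1 was at 521 ± 273 against 1039 ± 204 CPM (SD, n = 3), with a log2 fold change of -0.997 ± 0.42 (SE) and an adjusted p of 0.738 in edgeR. Without biphenyl alone replicate 2 it was -1.58, with an adjusted p of 0.0816. The other copy, sdhA_2, had the opposite sign, at 0.53 ± 0.44 (SE), and did not pass. Its value was 0.81 without biphenyl alone replicate 2, 0.11 without biphenyl alone replicate 1 and 0.23 without biphenyl plus glucose replicate 2. Both the chaperone list and sufC gave 0 calls, over all genes and adjusted over the list alone.

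In all, edgeR called 0 of 3143 genes, with 202 at an unadjusted p under 0.05 where 157 were expected. Splits of the same 6 libraries that mix the groups gave between 29 and 1168 such genes, so the count of 202 shows no excess. DESeq2 called 1, limma-voom 0 and limma on deposited TPM 1. Groups did not overlap in 238 genes (7.57%), where chance gives 10%. Leaving out biphenyl alone replicate 2 gave 3 calls, and leaving out control replicate 2, control replicate 3 or biphenyl plus glucose replicate 2 gave 1 each.

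Across all 3 groups together, edgeR called 0 of 3143 genes and 30 with the block, with 285 at an unadjusted p under 0.05. DESeq2's likelihood ratio test called 11, limma-voom 0 and limma on deposited TPM 0. Without biphenyl alone replicate 2 the count was 98, and without biphenyl plus glucose replicate 1 it was 29. It was 3 without biphenyl plus glucose replicate 2 and 1 without control replicate 1. The first principal component (37.7% of variance) placed the controls between -3.60 and 3.73. Biphenyl plus glucose replicate 1 and biphenyl alone replicates 1 and 3 lay at -25.0, -23.8 and -17.8, and the other 3 biphenyl libraries between 14.2 and 28.5.

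**Figure D3:**
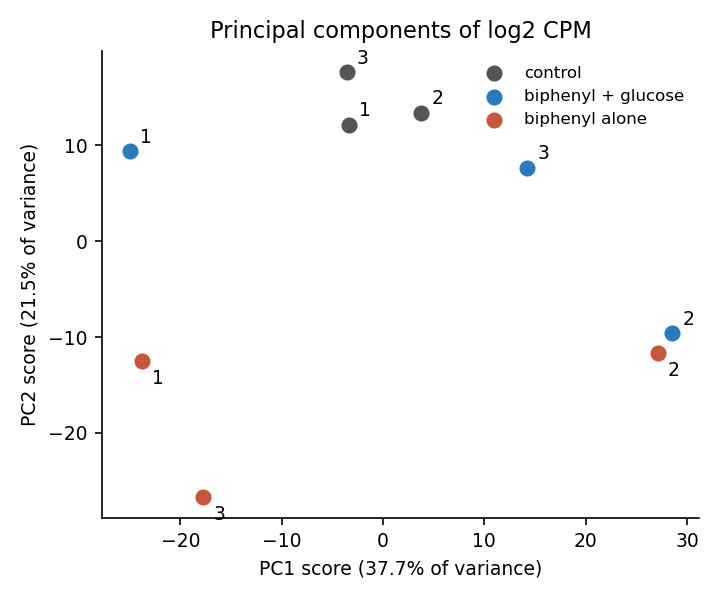
Scores of the 9 libraries on the first and second principal components of log2 CPM, in units of the components, coloured by group and marked with the replicate number. The controls lie between -3.60 and 3.73 on the first component, the biphenyl libraries outside that range on both sides, and the second component (21.5%) runs from 12.2 to 17.7 in the controls and from -26.7 to -11.6 with biphenyl alone.

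The 2 comparisons with control shared their control libraries. Their log2 fold changes correlated at 0.564 across 3143 genes, which are not independent replicates. Unchanged groups simulated with shared controls gave 0.456 on average (0.419 to 0.486 in 100 draws). The covariance was 0.150 against a simulated 0.0915, a difference of 0.0583. With the block, FRAEUI1C_RS24605 was the 1 gene that rose in both, where independent lists of 2 and 17 genes would share 0.0108. Simulated unchanged groups with the block had at most 2 calls in the first comparison and 0 in the second over 20 sets, so they give no chance value for that overlap. At an unadjusted p under 0.05, 97 genes were shared in one direction (51 higher, 46 lower), against 25.25 on average in the 20 simulated sets (highest 34), and independent lists would share 8.91 and 7.81. The controls could not be split with 2 libraries in each part, so the part due to shared controls could not be measured directly. The simulated sets include shared controls, but with the same dispersion of a gene in all groups. Control pairs had a chi-square per degree of freedom of 1.79 to 2.66, and pairs within the biphenyl groups 2.38 to 8.04. The simulated values are therefore not an exact reference. The simulated groups also left batch out. Deviations that same-batch libraries share, estimated from these 3 batches, would add 0.0354 to the covariance. Without the block no gene was shared at the adjusted threshold with all libraries, and 1 was without control replicate 1. At an unadjusted p under 0.05, 61 were shared without the block (36 higher, 25 lower), against 26.45 on average in the simulated sets (highest 39), and independent lists would share 5.88 and 3.84.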

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

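The tests of batch, of exchanged labels and of background, and the comparisons by splits without the block for each pair of groups, were chosen after their results had been seen. The runs, the length and background corrections and the fits that leave out biphenyl alone replicates 2 or 3 with the block were added after seeing the data.

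In data that the comparisons do not use, the share of reads on the 6 multicopy rows was 97.4% on average with biphenyl plus glucose, and each of its 3 libraries (at least 96.6%) lay above the highest control (96.5%). The two-sided exact permutation p was 0.1, the smallest that 3 against 3 libraries can give.

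The 61 genes that passed with the block for biphenyl alone against control were weighed against gene length bias and a flat background of reads, since the 44 lower ones were short and biphenyl alone replicate 3 had the most reads in the least expressed genes. Removing a length trend per library left 0.937 of the median log2 fold change of the 44 lower genes and 0.901 of that of the 17 higher ones. Subtracting a length-proportional background, with the same genes tested, left 0.987 for the lower ones. The 2 corrections moved the log2 fold changes of other tested genes by a median of 0.098 and 0.0426, so the trends as estimated are small beside these folds. The genes were chosen in the same data for large folds, so the ratios do not show that their calls are free of these trends. For the 17 the fold had to grow on subtraction (ratio 1.23), since each exceeded the background's own log2 ratio of 1.25 before TMM scaling. The background difference, as estimated, amounted to a median of 5.83% (highest 28.4%) of their CPM difference. These genes were chosen for a large rise in the same data, so a small share was likely beforehand. It does not exclude a background as a part of their calls. Calls still fell, to 32 of 44 and 8 of 17 with length offsets and to 26 of 44 and 5 of 17 after subtraction over the same genes. With the count filter applied afresh after subtraction, 19 of 44 and 1 of 17 passed, with 12 of the 17 still tested. Over the same genes, subtraction took the median log2 fold change from -1.76 to -1.74 for the 44 (median SE 0.40 to 0.41). For the 17 it went from 1.78 to 2.19 (0.46 to 0.61). Median p in the blocked fit rose from 0.000169 to 0.000460 and from 0.000438 to 0.00118. After subtraction 456 genes had an unadjusted p under 0.05, against 539 before. These effects on the adjusted p were not separated. A response to the carbon source, as the design names, stays open. The blocked fit tests the difference between the groups (smallest adjusted p 0.00142, and 539 genes at p under 0.05 where 157 were expected) but not its cause. Its spread may be too small for this comparison, since batch deviations were shared mainly between the biphenyl groups. Without the block, splits that mix these groups gave up to 298 genes at p under 0.05, so 157 is no firm chance value. The 4 splits of the 6 libraries that part all same-batch pairs are too few for a share under 0.05. They gave 61 genes for the real split and 1 for the highest other, and 1 split of 4 reached 61.

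A structure of the samples that the labelled groups do not follow called far more genes than any comparison did, and no biological explanation of it was tested. When the 6 biphenyl libraries were split so that biphenyl plus glucose replicate 1 stood with biphenyl alone replicates 1 and 3, edgeR called 689 genes, against 0 for the real groups and 0 for every other split of these libraries. After background subtraction 559 of the 689 were called (a share of 0.811; 63 were no longer tested), and 632 with the same genes tested, where the median absolute log2 fold change was 1.39 before and 1.48 after (median SE 0.38 and 0.41), which argues against a flat background as the whole cause. The split leaves both same-batch pairs of batches 1 and 2 together and parts that of batch 3, and the controls, which it does not use, leave batch open, since their deviations correlated with those of biphenyl libraries of their own batch at 0.0823 or more in batches 1 and 2. An exchange of the labels of biphenyl plus glucose replicate 1 and biphenyl alone replicate 2 would give the same split and cannot be told apart from other differences between libraries: the ratio of short to long multicopy reads overlapped under both labelings (exchanged groups differed by 0.00570), the second principal component and the genes with 0 reads (935 to 1351 against 330 to 905) parted the groups only as labelled, and the genes expected at 0 reads at an equal depth of 91038 reads only as exchanged.

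For each pair of groups the 10 splits of 6 libraries are too few for a share under 0.05. The real count was 0 in all 3, so 10 of 10 splits reached it, and the highest other split gave 0, 0 and 689 genes. With the block, 2 of 4 splits reached the real 2 genes for biphenyl plus glucose against control (highest other 4) and 2 of 4 the real 1 for biphenyl alone against biphenyl plus glucose (highest other 1). For all 3 groups together the real count was 0, which all 100 of 100 drawn splits reach by construction (highest other 627), while 14 of 100 had as many genes at an unadjusted p under 0.05 as the real 285. With the block, 3 of the 36 regroupings within batches reached the real 30 genes (highest other 56), so chance cannot be excluded.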

How the results depend on the processing

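The fits on runs of genes, with length offsets, with background subtraction, and with the replicate block but without biphenyl alone replicates 2 or 3 were chosen after seeing the data. The result that no gene passed in biphenyl plus glucose against control, in biphenyl alone against control, in biphenyl alone against biphenyl plus glucose, and over all 3 groups held with DESeq2's size factors, upper-quartile factors and the multicopy rows kept. A minimum log2 fold change of 1 can only remove calls from the main fit, so its count was fixed in advance. The replicate block (batch) gave 2, 61, 1 and 30 genes, DESeq2 1, 20, 1 and 11, and no count filter 1, 55, 5 and 38. A minimum of 10 CPM in 3 libraries, which at this depth kept 6459 genes and so was looser than the main filter, gave 0, 29, 1 and 18. Of the single changes, limma-voom gave 4, the fit of only the 2 groups 3 and unique reads 2 for biphenyl alone against control, and limma on TPM gave 1 for biphenyl alone against biphenyl plus glucose. Leaving out 1 library gave 0 to 1, 0 to 253, 0 to 3 and 0 to 98 genes. A lone pair left in a group was fitted with the pooled spread. The overlap of the 2 comparisons with control was 0, 1 with the replicate block and 0 to 1 when 1 library was left out. Runs of genes gave 1 for biphenyl alone against control, and runs with the replicate block gave 3, 70 and 1. With the replicate block, leaving out biphenyl alone replicate 3 gave 4, 12 and 1, leaving out biphenyl alone replicate 2 gave 3, 235 and 20, length offsets gave 3, 48 and 1, background subtraction gave 0, 20 and 1, and over the same genes 1, 31 and 1, and runs with background subtraction gave 1, 26 and 1. All 20 genes of DESeq2 for biphenyl alone against control are among the 61 of the block, as are 45 of the 253 found without biphenyl alone replicate 2. The cause was not tested. The 15 named results kept their direction in all 383 alternatives computed and passed in 95. They were chosen for the smallest p in the same libraries, so a kept direction is no independent support. Upper-quartile factors moved the median log2 fold change of biphenyl alone against control from 0.06 to 0.18 and that against biphenyl plus glucose from -0.03 to 0.10. The block changed no call of a symbol group or planned list. The planned counts of gene lists and their alternatives were not run, because no list had 5 members, and the fit of only the 2 groups does not apply to 3 groups. Alternatives for files without counts did not apply.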

Other observations

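The genes given here were chosen after their values were seen. Some abundant named transcripts varied widely within biphenyl alone. Across biphenyl alone replicates 1, 2 and 3, dnaK was at 5720, 8218 and 2297 CPM, where the controls lay between 7674 and 8546 CPM, values that are uncertain because 29.7% of its reads map elsewhere too. The elongation factor gene fusA, the ribosomal protein gene rpsA and the protease gene clpP had SDs of 3956, 3095 and 617 CPM within biphenyl alone, against 930, 815 and 11.2 CPM in controls (n = 3 each).

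The cofactor synthesis gene cobN and the amine oxidase gene tynA had higher means with biphenyl alone than in controls, at 112 ± 25.3 against 72.6 ± 26.7 and 91.4 ± 52.2 against 44.4 ± 2.06 CPM (SD, n = 3), and did not pass. The glutamate synthase gene gltD was at 281 ± 23.7 against 363 ± 37.6 CPM and did not pass. The transport gene livG had 26 reads in all libraries together and was not tested.

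Of the 3 copies of the multicopy genes, the pair at 5787441 to 5792432 held between 0.481% and 1.17% of the multicopy reads in each library, far less than an equal share. Of the reads counted there, 98.5% (3137 bp gene) and 99.4% (1510 bp gene) map to other places as well. These counts therefore do not show how much each copy was expressed.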
